A study of Homo sapiens with 171 samples.

How the data were processed

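RNA of 5 human pancreatic ductal adenocarcinoma cell lines was measured in 55 groups: normoxia on days 0, 1, 3, 7, 9 and 14 and hypoxia at 1% oxygen on days 1, 3, 7, 9 and 14, with 3 labelled replicates each. Per the labels' protocols, cells were lysed in the well, hypoxic cells stayed at 1% oxygen throughout, and the lines grew in different media. Libraries were made from fragmented RNA by oligo-dT priming and template switching, with a sample index and a unique molecular identifier (UMI) in the switching oligo, and pooled after reverse transcription. Per the submitters' processing notes, bcl2fastq was used and reads were placed on GRCh38. The aligner, the counting tool, the annotation, the use of UMIs and the strand are not given in the sources used here.

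The deposited files hold raw whole-number counts per Ensembl gene, 1 file per sample, and whether these are reads or collapsed UMIs is not stated. There were 165 files of cell line libraries and 3 of controls without template. Another 3 samples had no file. The files carry 3 lists of genes, of 29188, 29015 and 28618 identifiers, which follow the plate. In content 114 files were distinct and 54 pairs were identical, 17 of them across cell lines, 8 across oxygen levels and 2 with a control. In every identical pair exactly 1 file had the gene list of the plate in its label, and that file was kept. This left out 52 cell line files, 51 labelled replicate 1 and 1 labelled replicate 2. A further library (PACADD188 normoxia day 7 replicate 2, 17173 counts) held under 5% of the median total and was left out. The design fixed before the data were examined had 165 libraries in groups of 3, and the 112 kept libraries (4, 53 and 55 of replicates 1, 2 and 3) form 49 groups of 2, 4 of 3 and 2 of 1. No file content was moved to another label. A copy can also hide a true library that is missing from the deposit, and a wrong label among the unpaired files cannot be seen this way.

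Genes missing from a plate's list were set to 0 there. The 7322 genes not in all 3 lists held 0.00404% of the counts. Of the 32829 identifiers, 32447 had a symbol, and coordinates are those of GENCODE release 29 (GRCh38), which holds 32693 of them. Kept libraries had 648983 to 6270218 counts and 13184 to 18587 detected genes.

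Counts were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): TMM scaling, 1 mean per group, quasi-likelihood F-tests, and genes with at least 10 counts (scaled to the median library) in at least 2 libraries and 15 in total. Each line was fitted alone (residual degrees of freedom 10, 12, 13, 11 and 11 for AsPC1, PACADD188, Panc0203, Panc0403 and Panc1, biological coefficient of variation 0.1115, 0.1196, 0.1298, 0.1129 and 0.1151). All libraries were fitted together for the mean of lines, the F test between lines, day 14 minus day 1 and day 0 (57 degrees of freedom, 0.1194). Groups of 1 library take their spread from the rest of the fit. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the genes tested in that contrast. An SE was taken from the log2 fold change and its F statistic. CPM use the effective library sizes of the fit of all libraries, and a group mean ± SD of CPM is over libraries. The p-values measure the spread between these libraries alone. Lines were not drawn at random, so no test carries over to PDAC at large.

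Gene lists, fixed before the data were examined, were tested with camera (limma) at a preset correlation of 0.01 and adjusted within each contrast, beside the members called over all genes and adjusted over the list alone. Shares of counts were compared by a 2-sided permutation test with 1e+05 resamples. Correlations of fold changes are Pearson r.

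Genes were named by a rule set before the data were examined: 6 fixed genes, and then, among called genes with at least 20 counts on average in the higher group, the largest rises and falls. These were 12 and 12 for the mean of lines (same sign in all 5), 5 and 5 for each line (same sign on all days), 2 and 2 for each line in the F test, 8 and 8 for day 14 minus day 1, 3 and 3 for day 0 and for normoxic time, and up to 4 called members of a described list. Genes without a symbol and sex-linked or antigen receptor genes were passed over, and fewer were named where the text would become a list of values.

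Replicate numbers are plate numbers per the labels, so a fit with the plate as a block was the alternative to the unblocked design. Between groups of a line, the deviation of plates 2 and 3 from the group mean correlated at a median of 0.0684, 0.0646, 0.0775, 0.0831 and 0.0596 in the 5 lines.

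The scripts were tested on simulated counts with 200 changed genes. For the Panc0203 mean of days (12243 genes), 190 genes were called, 10 of them unchanged. Calls were made for 76.1, 95.5 and 98.5% of the 1.5-, 2- and 4-fold changes. On Panc0203 day 9 the figures were 8.96, 40.3 and 86.4% with 1 false call of 91. In the fit of all libraries (14107 genes) 91, 92.5 and 86.4% were recovered in the mean of lines with 4 false calls of 184, and the F test called 0 genes where none differed between lines. Camera called 1 of 1 changed list and 0 of 50 unchanged lists.

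Alternatives were DESeq2 1.42.0, RLE scaling, no filter beyond 1 count, a filter at a mean of 20 counts, the plate block, thinning to the shallowest library, leaving out each plate, fits of the compared libraries only, an estimated correlation and fry for lists, and calls at least 2-fold. Added after the files were seen were all libraries as labelled, the shallow library kept, and the Panc0203 library carrying PACADD188 transcripts, each library, or 1 line on 1 plate left out. Regroupings were 60 per line and 24 in the fit of all libraries. Scripts ran under Python 3.11.15 and R.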

Results

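RNA of 5 human pancreatic ductal adenocarcinoma (PDAC) cell lines, AsPC1, PACADD188, Panc0203, Panc0403 and Panc1, was counted per gene after growth at atmospheric oxygen (normoxia) or at 1% oxygen (hypoxia). Normoxic cells were sampled on days 0, 1, 3, 7, 9 and 14 and hypoxic cells on days 1, 3, 7, 9 and 14, which makes 55 groups with 3 labelled replicates each, numbered by plate. Of the 168 count files, 54 pairs were identical in every value, none of them within a group, and the copies carried the label of a plate whose gene list they did not have. After 52 such files and 1 library of 17173 counts were left out, 112 libraries of cell lines remained, 4 from plate 1, 53 from plate 2 and 55 from plate 3. Of the groups, 49 held 2 libraries, 4 held 3, and AsPC1 hypoxia day 14 and PACADD188 normoxia day 7 held 1. Total counts ran from 648983 to 6270218 per library with a median of 2063732, and levels are given as CPM, the count scaled to the effective total of its library. Hypoxic libraries were shallower in every line, for example 1551103.5 against 2539469.5 counts at the median in Panc0403 over days 1 to 14. The control without template on plate 3 held 146 counts over 125 genes. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries. A Panc0203 library (normoxia day 7 replicate 2) held transcripts that mark PACADD188, at a median of 34.4% of their PACADD188 level, and was kept.

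Across the mean of the 5 lines and 5 days, the 6 genes chosen in advance split into 4 that were higher in hypoxia and 2 that were lower (log2 fold change ± SE, 51 hypoxic and 49 normoxic libraries). CA9 (ENSG00000107159, chromosome 9, 35673856 to 35681159), a carbonic anhydrase and a known target of the hypoxia-inducible factors (HIF), rose by 4.18 ± 0.38. NDRG1 (ENSG00000104419, chromosome 8, 133237171 to 133302022), another HIF target, rose by 3.28 ± 0.051. The glucose transporter gene SLC2A1 (ENSG00000117394, chromosome 1, 42925375 to 42959176) rose by 1.38 ± 0.022, and VEGFA (ENSG00000112715, chromosome 6, 43770184 to 43786487), an angiogenic growth factor, by 0.77 ± 0.04. HIF1A (ENSG00000100644, chromosome 14, 61695513 to 61748259) and EPAS1 (ENSG00000116016, chromosome 2, 46293667 to 46386703), which encode the oxygen-regulated HIF subunits, changed by -0.55 ± 0.033 and -0.31 ± 0.033. Coordinates are those of the GRCh38 gene annotation and span each whole gene. In AsPC1, where it was highest, CA9 averaged 374 ± 192 CPM in hypoxia (SD, n = 9) and 73.8 ± 41.9 CPM in normoxia (n = 10). In Panc1 it stood at 1.33 ± 0.628 and 0.166 ± 0.329 CPM, under the level tested within that line. EPAS1 had the highest adjusted p of these genes, 1.86e-12 (edgeR quasi-likelihood test, Benjamini-Hochberg).

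In this mean of lines, 4524 of 14312 genes were called, 2060 higher and 2464 lower in hypoxia, and 88 of them moved at least 2-fold, 82 up and 6 down. Beside the 6 genes, rises with the same sign in all 5 lines included MIR210HG, the host transcript of a hypoxia-induced microRNA, at 2.89 ± 0.11. ANGPTL4, a regulator of lipoprotein lipase, rose by 2.88 ± 0.10, STC1, a secreted glycoprotein hormone, by 2.86 ± 0.19, and ANKRD37 by 2.63 ± 0.076. IGFBP3, a carrier of insulin-like growth factors, rose by 2.50 ± 0.052, and SPAG4 and the collagen-modifying enzyme PLOD2 by 2.15 ± 0.12 and 2.06 ± 0.29. PFKFB4, ENO2 and PDK1 of glucose metabolism rose by 2.66 ± 0.15, 2.06 ± 0.13 and 1.97 ± 0.048. Among the falls, FOXA1, a transcription factor of endodermal tissues, changed by -1.32 ± 0.13 and averaged 13.9 ± 2.53 CPM in hypoxic (SD, n = 11) against 28.1 ± 10.6 CPM in normoxic PACADD188 (n = 9). The microsomal epoxide hydrolase EPHX1 changed by -0.95 ± 0.098, TAF9B by -0.92 ± 0.065, RASSF6 by -0.89 ± 0.22, TPD52L1 by -0.82 ± 0.18, LINC03060 by -0.97 ± 0.21 and the mitochondrial arginase ARG2 by -0.74 ± 0.18. The growth factor gene EREG changed by -0.73 ± 0.046, and the mitochondrial tRNA genes MT-TA, MT-TS1, MT-TP and MT-TC by -1.28 ± 0.13, -1.23 ± 0.13, -0.84 ± 0.081 and -0.82 ± 0.12. RASSF6 had the highest adjusted p of these genes, 0.000964, in edgeR's quasi-likelihood test. Calls ended without 1 line on 1 plate for PLOD2 (AsPC1 replicate 2, log2 fold change then 1.85) and ARG2 (PACADD188 replicate 2, -0.78). They ended for LINC03060, RASSF6 and TPD52L1 without Panc1 replicate 2 (-0.99, -0.91 and -0.75). Thinning ended these 5 and those of PFKFB4 and SPAG4.

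Glucose metabolism rose as a group: 20 of 21 glycolysis and glucose uptake genes were higher in hypoxia and none was lower (20 adjusted over the list alone, below list-adjusted, camera adjusted p = 6.68e-67, such values written q from here on). PFKFB3 was among them at 1.53 ± 0.044. Of the other HIF targets 27 of 38 rose and 1 fell (27 and 1 list-adjusted, q = 2.95e-61). Of the oxygen-sensing genes 3 of 7 fell and none rose (3 list-adjusted, q = 0.0234), although the median of that list was 0.018. VHL, which targets HIF for degradation, stood at -0.29 ± 0.072. The unfolded protein response list, which holds endoplasmic reticulum chaperones, had 14 of 20 members up and none down (14 list-adjusted, q = 3.92e-09), for example HSP90B1 at 0.41 ± 0.021. Targets of the stress factor ATF4 were lower, 13 of 20 down and 2 up (14 and 2 list-adjusted, q = 1.32e-06), with 14 and 15 down on days 9 and 14 and 2, 2 and 1 on days 1, 3 and 7 (4 and 1 up on days 3 and 7). The serine synthesis enzyme PSAT1 stood at -0.71 ± 0.04, SESN2 at -0.60 ± 0.09 and the cystine transporter SLC7A11 at -0.48 ± 0.057. Nuclear genes of oxidative phosphorylation fell in 57 of 63 cases with none up (58 list-adjusted, q = 4.44e-28), NDUFA4 by -0.38 ± 0.023. Of the genes encoded in mitochondria 7 of 11 fell (8 list-adjusted, q = 0.000104), MT-ND2 by -0.34 ± 0.037, with 6 and 9 down on days 9 and 14 and 2 on day 3.

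Among growth and identity groups, 26 of 40 G2/M genes rose and none fell (27 list-adjusted, camera adjusted p = 1.41e-08), with 32 and 40 up on days 9 and 14 but 8 and 23 down on days 1 and 3. The cytokinesis gene ANLN stood at 0.70 ± 0.031 and UBE2C at 0.46 ± 0.024. Matrix genes rose in 14 of 30 cases (15 list-adjusted, q = 2.84e-05), with the laminin chain LAMB3 at 1.00 ± 0.086 and PLAUR at 0.82 ± 0.046. Mesenchymal genes rose in 9 of 20 (10 list-adjusted, q = 3.06e-08), with vimentin (VIM) at 0.62 ± 0.053. Metallothioneins rose in 5 of 7 (5 list-adjusted, q = 0.000285), with MT1X at 0.95 ± 0.035. NRF2 antioxidant genes fell in 16 of 22 (16 list-adjusted, q = 2.02e-09), including G6PD at -0.51 ± 0.049. Fatty acid synthesis genes fell in 8 of 13 with 1 up (8 and 1 list-adjusted, q = 0.0024), MID1IP1 by -0.50 ± 0.042. Ribosome biogenesis genes fell in 13 of 27 and rose in 3 (15 and 3 list-adjusted, q = 0.00806, adjusted p = 0.0562 with an estimated correlation), with 20 and 21 down on days 1 and 3 and 9 up on day 9. Ribosomal proteins rose in 14 of 72 (11 list-adjusted, q = 0.0234, adjusted p = 0.921 with an estimated correlation). Immediate early genes, which also respond to handling, rose in 14 of 16 cases in the same libraries (14 list-adjusted, q = 7.96e-12), with FOS at 0.98 ± 0.091 and JUN at 0.74 ± 0.033. The classical PDAC list passed as lower (q = 0.00588) with 1 member of 22 down, AGR2 at -0.60 ± 0.033, and 1 up (1 down and 0 up list-adjusted). With the plate as a block its q was 0.809. The lists of DNA replication, DNA repair, cholesterol, interferon, MHC class I, cytokine, p53, heat shock, basal-like, epithelial, mucin and fibroblast genes did not pass camera, with adjusted p from 0.102 to 0.989. The other calls held with an estimated correlation.

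**Figure D1:**
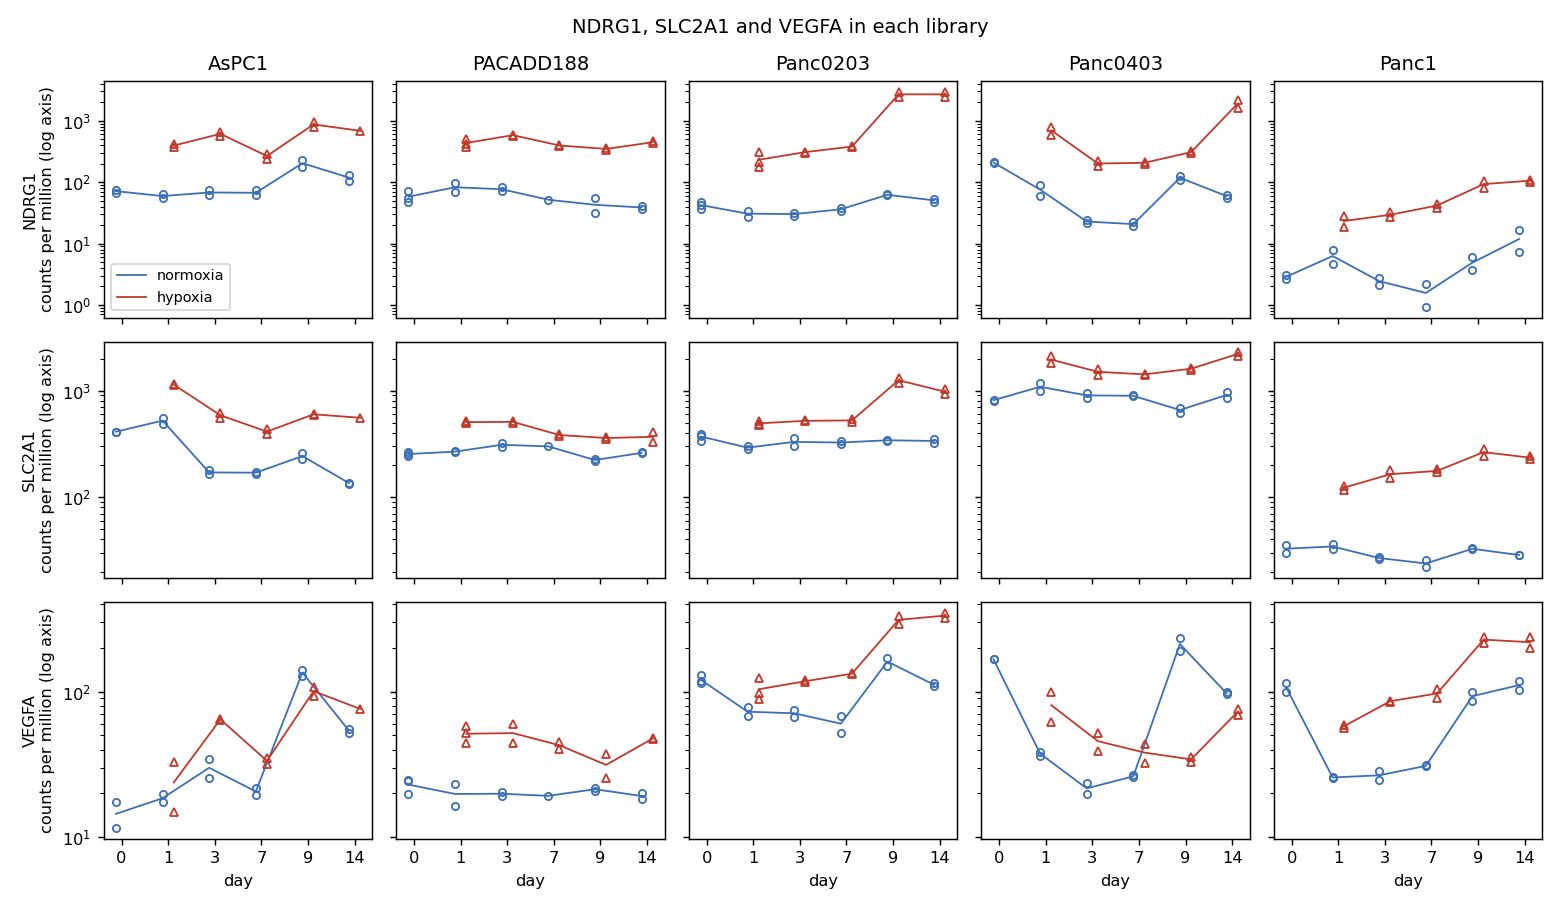
CPM of NDRG1, SLC2A1 and VEGFA (log axis) against day for each cell line, with a point for each hypoxic and normoxic library and lines through the group means. NDRG1 lay above its normoxic level on every day in all 5 lines, while VEGFA in Panc0403 averaged 34.2 CPM in hypoxia and 212 CPM in normoxia on day 9.

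In AsPC1, 2306 of 11634 genes were called over the 5 days, 1208 up and 1098 down, of which 206 moved at least 2-fold (147 up, 59 down; 9 hypoxic and 10 normoxic libraries). ANKRD37, a HIF target, rose by 3.67 ± 0.26 (log2 fold change ± SE), MIR210HG by 3.48 ± 0.26, the secreted trefoil factor TFF3 by 3.02 ± 0.074 and the apolipoprotein gene APOL1 by 2.85 ± 0.12. Falls with 1 sign on all days included the aldo-keto reductase AKR1B10 at -2.98 ± 0.19, the glutathione peroxidase GPX2 at -2.53 ± 0.19, the metal-binding proteins MT1G and MT1M at -2.37 ± 0.14 and -1.53 ± 0.14, and the aldehyde dehydrogenase ALDH3A1 at -1.44 ± 0.12. Of the genes chosen in advance CA9, NDRG1, SLC2A1 and VEGFA rose by 2.46 ± 0.084, 2.52 ± 0.076, 1.52 ± 0.047 and 0.45 ± 0.11, EPAS1 changed by -0.30 ± 0.085, and HIF1A was not called at -0.21 ± 0.079 (adjusted p = 0.0655, edgeR). EPAS1 had the highest adjusted p of these genes, 0.0179, by edgeR, and lost its call without normoxia day 3 replicate 2 (then -0.23). NDRG1 ran from 2.01 ± 0.17 on day 7 to 3.16 ± 0.17 on day 3. On days 1, 3, 7, 9 and 14, 198, 932, 145, 1082 and 309 genes were called, and leaving out 1 library gave day 1 49 (normoxia replicate 2), day 3 323 (hypoxia replicate 2), day 7 50 (hypoxia replicate 3), day 9 503 (normoxia replicate 3) and day 14 155 (normoxia replicate 2). The plate as a block gave 347 on day 1.

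AsPC1 lowered lipid and antioxidant groups. Fatty acid synthesis fell (12 of 12 down, 12 list-adjusted, q = 2.62e-15), the desaturase SCD by -1.27 ± 0.063. Cholesterol synthesis fell (9 of 24 down, 14 list-adjusted, q = 5.57e-06), INSIG1 by -0.58 ± 0.086, as did NRF2 genes (16 of 21 down, 17 list-adjusted, q = 2.6e-21), AKR1C1 by -1.20 ± 0.072. Metallothioneins fell (6 of 7 down, 6 list-adjusted, q = 1.44e-25), and ribosome biogenesis genes (1 up and 8 down of 27, 1 and 12 list-adjusted, q = 0.00143). ATF4 targets were lower (10 of 16 down, 11 list-adjusted, q = 5.21e-09), PSAT1 by -1.10 ± 0.13 and SESN2 by -1.12 ± 0.24. All 16 were down on day 9 and 1 on day 14. On day 9 the mean of the list (log2 CPM + 1) was 6.44 and 6.69 in normoxia and 4.42 and 4.45 in hypoxia, and on day 7 it was 4.53 and 4.69 in normoxia. Glycolysis rose (19 of 20 up, 19 list-adjusted, q = 3.77e-46), the glucose transporter SLC2A3 by 4.36 ± 0.62, and other HIF targets with it (24 of 28 up, 25 list-adjusted, q = 1.41e-79). Matrix genes rose (15 up and 1 down of 21, 15 and 1 list-adjusted, q = 2.87e-14), the anchoring collagen COL7A1 by 1.75 ± 0.34. Mesenchymal genes rose (6 up and 1 down of 11, 7 and 2 list-adjusted, q = 2.36e-05), AXL by 0.75 ± 0.096, and basal-like genes (5 up and 1 down of 12, 5 and 1 list-adjusted, q = 0.000121), the keratin KRT7 by 1.80 ± 0.21. The classical list also passed as higher (4 up and 3 down of 17, 6 and 3 list-adjusted, q = 8.2e-05) with a median of -0.0063. Ribosomal proteins passed as higher (48 of 72 up, 61 list-adjusted, q = 1.37e-15, adjusted p = 0.19 with an estimated correlation), as did immediate early genes, which handling can raise (4 up and 2 down of 15, 4 and 2 list-adjusted, q = 0.0247, adjusted p = 0.0839 with an estimated correlation). SESN2 had the highest adjusted p of these genes, 0.00235, in edgeR, and the lists were tested with camera.

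PACADD188 had 2821 of 11815 genes called, 1466 up and 1355 down, with 306 at least 2-fold (218 up, 88 down; 11 hypoxic and 9 normoxic libraries). NDUFA4L2, a mitochondrial protein induced by HIF, rose by 5.79 ± 0.42, the receptor phosphatase PTPRB by 2.63 ± 0.097, the collagen cross-linking oxidase LOX by 2.63 ± 0.12 and MIR210HG by 2.52 ± 0.20. Among the falls were the steroid reductases AKR1C2 and AKR1C1 at -3.05 ± 0.076 and -2.32 ± 0.065, the adhesion receptor ADGRG2 at -2.27 ± 0.29, the trefoil factor TFF1 at -2.17 ± 0.54 and MT-TS1 at -2.10 ± 0.27. CA9, NDRG1, SLC2A1 and VEGFA rose by 4.52 ± 0.19, 2.98 ± 0.10, 0.64 ± 0.051 and 1.16 ± 0.11, while HIF1A and EPAS1 changed by -0.50 ± 0.06 and -0.68 ± 0.058. TFF1 had the highest adjusted p of these genes, 0.00493, in edgeR. NDRG1 ran from 2.42 ± 0.19 on day 1 to 3.54 ± 0.22 on day 14. On days 1, 3, 7, 9 and 14, 206, 695, 253, 1815 and 1195 genes were called, and leaving out 1 library gave day 1 106 (normoxia replicate 3), day 3 268 (normoxia replicate 2), day 7 147 (hypoxia replicate 3), day 9 896 (normoxia replicate 2) and day 14 641 (hypoxia replicate 2). Normoxia on day 7 had a single library.

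NRF2 genes fell in PACADD188 (20 of 21 down, 20 list-adjusted, q = 4.3e-52, camera), AKR1C3 by -1.86 ± 0.087. Nuclear oxidative phosphorylation fell with it (55 of 63 down, 58 list-adjusted, q = 2.02e-27), cytochrome c (CYCS) by -0.59 ± 0.058. Classical PDAC genes fell (7 of 9 down, 7 list-adjusted, q = 1.2e-08), the disulfide isomerase AGR2 by -1.53 ± 0.096 and ANXA10 by -1.52 ± 0.10. Mesenchymal genes rose (13 up and 1 down of 18, 15 and 1 list-adjusted, q = 4.59e-28), the actin-binding TAGLN by 2.34 ± 0.17 and SPARC by 1.59 ± 0.14. Matrix genes rose (18 up and 1 down of 25, 20 and 2 list-adjusted, q = 7.35e-18), PLAU by 1.51 ± 0.11, and metallothioneins (6 of 6 up, 6 list-adjusted, q = 5.61e-23), MT1E by 1.72 ± 0.084. Glycolysis rose (17 of 21 up, 18 list-adjusted, q = 1.54e-31), PFKFB4 by 2.43 ± 0.28, with other HIF targets (32 of 35 up, 32 list-adjusted, q = 2.42e-83). The unfolded protein response rose (8 up and 1 down of 20, 8 and 1 list-adjusted, q = 0.00907), and so did immediate early genes, a handling marker (9 of 15 up, 9 list-adjusted, q = 7.26e-08), JUN by 0.97 ± 0.073. DNA replication fell (17 of 40 down, 19 list-adjusted, q = 0.000344), GINS3 by -0.50 ± 0.093, and fatty acid synthesis with it (2 up and 5 down of 13, 2 and 8 list-adjusted, q = 0.00243). Basal-like genes were not called without the plate (q = 0.0542) and were with it as a block (0.026).

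Panc0203 had 2787 of 12420 genes called, 1542 up and 1245 down, with 305 at least 2-fold (236 up, 69 down; 11 hypoxic and 10 normoxic libraries). The scavenging chemokine receptor ACKR3 rose by 5.36 ± 0.77, CA9 by 4.48 ± 0.29, NDRG1 by 4.16 ± 0.096, SLC2A3 by 4.12 ± 0.39 and the vasoactive peptide gene EDN2 by 3.84 ± 0.22. Falls included TAF9B at -2.08 ± 0.18, the mitochondrial tRNA gene MT-TT at -1.82 ± 0.078, CCDC33 at -1.80 ± 0.42 and the prostaglandin E synthase PTGES at -1.74 ± 0.068, and CCDC33 was not called without normoxia day 1 replicate 2 (-1.06). The deiodinase DIO2 was lower (-3.19 ± 0.98, -2.37 without the library carrying PACADD188 transcripts, where it stood at 219.8 CPM against 6.66 CPM in the other library of that group), a call lost without normoxia day 1 replicate 2, day 1 replicate 3 or day 3 replicate 2. SLC2A1 and VEGFA rose by 1.10 ± 0.051 and 0.98 ± 0.067, HIF1A changed by -0.76 ± 0.075, and EPAS1 rose by 0.20 ± 0.062, a call lost under 5 alternatives (adjusted p up to 0.397). DIO2 had the highest adjusted p of these genes, 0.021, by edgeR. NDRG1 ran from 2.89 ± 0.22 on day 1 to 5.73 ± 0.23 on day 14. On days 1, 3, 7, 9 and 14, 109, 466, 387, 2520 and 2633 genes were called, and leaving out 1 library gave day 1 39 (normoxia replicate 2), 167 (hypoxia replicate 3), day 3 130 (normoxia replicate 2), day 7 172 (hypoxia replicate 3), 620 (normoxia replicate 3) and day 9 1481 (hypoxia replicate 2). The plate as a block gave 1041 on day 3 and 619 on day 7, and day 7 without the library carrying PACADD188 transcripts gave 190.

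In Panc0203 mitotic genes were higher in hypoxia (37 of 40 up, 38 list-adjusted, q = 4.53e-35, camera), ANLN by 1.42 ± 0.062 and the ubiquitin-conjugating UBE2C by 1.06 ± 0.049, with 25 and 40 up on days 9 and 14 and 1 down on day 3. The mean of the list (log2 CPM + 1) went from 7.14 and 7.08 on day 7 to 5.19 and 5.25 on day 9 and 5.15 and 4.94 on day 14 in normoxia, and from 7.31 and 7.26 to 5.92 and 5.83 and then 7.06 and 6.99 in hypoxia. Interferon-stimulated genes fell (22 of 35 down, 26 list-adjusted, q = 1.54e-08), IFI44L by -1.20 ± 0.12 and OAS2 by -0.85 ± 0.20, with 2, 23 and 27 down on days 7, 9 and 14. Glycolysis rose (21 of 21 up, 21 list-adjusted, q = 6.28e-84), ENO2 by 2.50 ± 0.17, with other HIF targets (33 up and 1 down of 34, 33 and 1 list-adjusted, q = 2.99e-135). Metallothioneins rose (4 of 5 up, 4 list-adjusted, q = 8.32e-28), MT1X by 2.48 ± 0.056, and matrix genes (12 of 22 up, 12 list-adjusted, q = 1.35e-09), the protease MMP9 by 2.38 ± 0.20. The unfolded protein response rose (10 up and 1 down of 20, 11 and 1 list-adjusted, q = 2.83e-05), the chaperone HSPA5 by 0.63 ± 0.064. Immediate early genes, which handling can raise, were up as well (10 of 15 up, 12 list-adjusted, q = 1.57e-10), JUN by 1.28 ± 0.066. Fatty acid synthesis fell (5 of 12 down, 8 list-adjusted, q = 0.000115), FASN by -0.78 ± 0.10, and so did heat shock proteins, another handling marker (7 of 12 down, 9 list-adjusted, q = 0.000347, adjusted p = 0.0585 with an estimated correlation).

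Panc0403 had 2444 of 11841 genes called, 1257 up and 1187 down, with 208 at least 2-fold (151 up, 57 down; 10 hypoxic and 10 normoxic libraries). CA9 rose by 6.23 ± 0.20, the largest CA9 change of the 4 lines tested, from 1.08 ± 1.31 to 99.9 ± 92.7 CPM (SD). STC1 rose by 4.19 ± 0.49, ANGPTL4 by 3.60 ± 0.27, NDRG1 by 3.22 ± 0.087 and SLC2A3, with which SLC2A14 (2.85 ± 0.23) shares sequence, by 2.57 ± 0.061. Among the falls with 1 sign on all days were ALDH1L2, a folate enzyme of mitochondria, at -2.02 ± 0.28, the serine enzyme PSAT1 at -1.38 ± 0.089, the cysteine synthesis enzyme CTH at -1.35 ± 0.19, the growth factor FGF2 at -1.31 ± 0.18 and the amino acid transporter SLC7A5 at -1.26 ± 0.11. SLC2A1 rose by 0.97 ± 0.054, HIF1A and EPAS1 changed by -0.72 ± 0.069 and -0.46 ± 0.076, and VEGFA was not called over the 5 days (-0.068 ± 0.093, adjusted p = 0.669). EPAS1 had the highest adjusted p of these genes, 0.000126, in edgeR. VEGFA moved from 1.04 ± 0.23 on day 1 and 1.11 ± 0.22 on day 3 to -2.60 ± 0.18 on day 9, when it averaged 34.2 ± 1.82 CPM in hypoxia and 212 ± 29.4 CPM in normoxia, and was -0.44 ± 0.19 on day 14. Its calls ended without hypoxia day 1 replicate 2 (then 0.72) and without hypoxia day 3 replicate 3 (0.87). NDRG1 ran from 1.42 ± 0.17 on day 9 to 5.00 ± 0.20 on day 14. On days 1, 3, 7, 9 and 14, 361, 380, 181, 3340 and 1569 genes were called, and leaving out 1 library gave day 1 176 (hypoxia replicate 3), day 3 103 (hypoxia replicate 2), day 7 39 (normoxia replicate 3), day 9 2114 (hypoxia replicate 3) and day 14 865 (normoxia replicate 2). With the plate as a block days 1, 3 and 7 had 567, 642 and 345.

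ATF4 targets were lower in hypoxia in Panc0403 (1 up and 17 down of 20, 1 and 17 list-adjusted, q = 1.93e-23, camera), with PHGDH at -1.49 ± 0.16 and 2, 19 and 17 down on days 7, 9 and 14. The mean of the list (log2 CPM + 1) went from 4.98 and 4.80 on day 7 to 6.80 and 6.87 on day 9 in normoxia and stayed at 4.74 to 4.77 in hypoxia. MHC class I genes fell (5 of 13 down, 6 list-adjusted, q = 0.000661), the immunoproteasome subunit PSMB9 by -0.72 ± 0.12 and the peptide transporter TAP1 by -0.57 ± 0.087, with 9 and 3 down on days 9 and 14. NRF2 genes (13 of 21 down, 14 list-adjusted, q = 5.07e-08) and cytokines (4 up and 6 down of 19, 4 and 7 list-adjusted, q = 0.00118), AREG by -0.93 ± 0.066, fell as well. Ribosomal proteins fell (34 of 72 down, 50 list-adjusted, q = 8.53e-10, adjusted p = 0.316 with an estimated correlation), RPL6 by -0.34 ± 0.063. Glycolysis (21 of 21 up, 21 list-adjusted, q = 1.45e-130) and other HIF targets rose (32 of 34 up, 33 list-adjusted, q = 6.25e-122). Metallothioneins rose (5 of 7 up, 6 list-adjusted, q = 2.25e-12), MT1X by 2.42 ± 0.069, and matrix genes (10 up and 2 down of 22, 11 and 2 list-adjusted, q = 0.000737). Classical PDAC genes rose (6 of 10 up, 6 list-adjusted, q = 3.31e-05), HNF4A by 1.27 ± 0.28 and TFF1 by 1.25 ± 0.23. DNA replication rose (16 up and 1 down of 40, 16 and 1 list-adjusted, q = 0.00117), CCNE2 by 0.67 ± 0.15, with 14 down on day 1 and 38 up on day 9. Both handling markers, immediate early (6 up and 1 down of 15, 7 and 1 list-adjusted, q = 0.00138, adjusted p = 0.0746 with an estimated correlation) and heat shock genes (7 up and 1 down of 12, 8 and 1 list-adjusted, q = 0.000888), also passed as higher.

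Panc1 had 2392 of 11668 genes called, 1395 up and 997 down, with 243 at least 2-fold (195 up, 48 down; 10 hypoxic and 10 normoxic libraries). IGFBP3 rose by 3.99 ± 0.18, PFKFB4 by 3.46 ± 0.20, DEPP1, a FOXO target in autophagy, by 3.40 ± 0.086, and MIR210HG by 3.22 ± 0.28. The stress cytokine GDF15 changed by -1.88 ± 0.14, MT-TS1 and MT-TC by -1.53 ± 0.23 and -1.46 ± 0.28, the peptidase PGPEP1 by -1.50 ± 0.16 and SH3BGRL2 by -1.46 ± 0.22. NDRG1, SLC2A1 and VEGFA rose by 3.58 ± 0.16, 2.68 ± 0.063 and 1.36 ± 0.062, HIF1A changed by -0.50 ± 0.065, and EPAS1 by -0.27 ± 0.078, a call lost without normoxia day 14 replicate 2 (then -0.19). EPAS1 had the highest adjusted p of these genes, 0.0182, in edgeR. NDRG1 ran from 1.96 ± 0.37 on day 1 to 4.81 ± 0.37 on day 7, and its day 1 value was not called without 1 of 2 libraries (1.65 and 1.51). On days 1, 3, 7, 9 and 14, 95, 490, 390, 1587 and 2273 genes were called, and leaving out 1 library gave day 1 55 (hypoxia replicate 2), day 3 176 (normoxia replicate 2), day 7 216 (normoxia replicate 2), day 9 878 (normoxia replicate 2) and day 14 1185 (normoxia replicate 2).

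Every gene of the unfolded protein response rose in Panc1 (20 of 20 up, 20 list-adjusted, q = 2.4e-13, camera), MANF, an endoplasmic reticulum growth factor, by 0.82 ± 0.094. The lipid groups rose, cholesterol synthesis (15 up and 0 down of 23, 19 and 1 list-adjusted, q = 1.17e-07), INSIG1 by 0.90 ± 0.052, and fatty acid synthesis (7 of 12 up, 7 list-adjusted, q = 0.00103), SCD by 0.61 ± 0.054. Glycolysis rose (20 of 20 up, 20 list-adjusted, q = 3.12e-93), HK2 by 2.33 ± 0.23, with other HIF targets (34 of 35 up, 35 list-adjusted, q = 4.16e-166), CA12 by 3.38 ± 0.32. Matrix genes rose (9 of 18 up, 9 list-adjusted, q = 2.4e-13), the collagens COL1A1 and COL5A1 by 2.65 ± 0.076 and 2.22 ± 0.16. Mesenchymal genes rose (10 up and 1 down of 14, 12 and 1 list-adjusted, q = 1.77e-07), TGFBI by 1.00 ± 0.059, and DNA replication (12 of 40 up, 12 list-adjusted, q = 0.00138), RRM2 by 0.83 ± 0.069, mostly on day 14 (24 up). Of the unfolded protein response 19 and 14 were up on days 9 and 14 and 1 on days 3 and 7 each, and of cholesterol synthesis 17 and 18 on days 9 and 14 and 2 on day 3. Cytokines rose (9 up and 3 down of 17, 9 and 5 list-adjusted, q = 0.00542), CCL20 by 2.58 ± 0.52. Immediate early genes, a handling marker, rose (10 of 16 up, 11 list-adjusted, q = 7.72e-10), EGR1 by 1.17 ± 0.12, and heat shock genes, another (8 of 12 up, 8 list-adjusted, q = 0.00569, adjusted p = 0.0631 with an estimated correlation). Epithelial genes passed as lower (1 up and 4 down of 14, 1 and 4 list-adjusted, q = 0.0323, adjusted p = 0.0631 with an estimated correlation, q = 0.0951 with the plate as a block) with a median of 0.00.

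**Figure D2:**
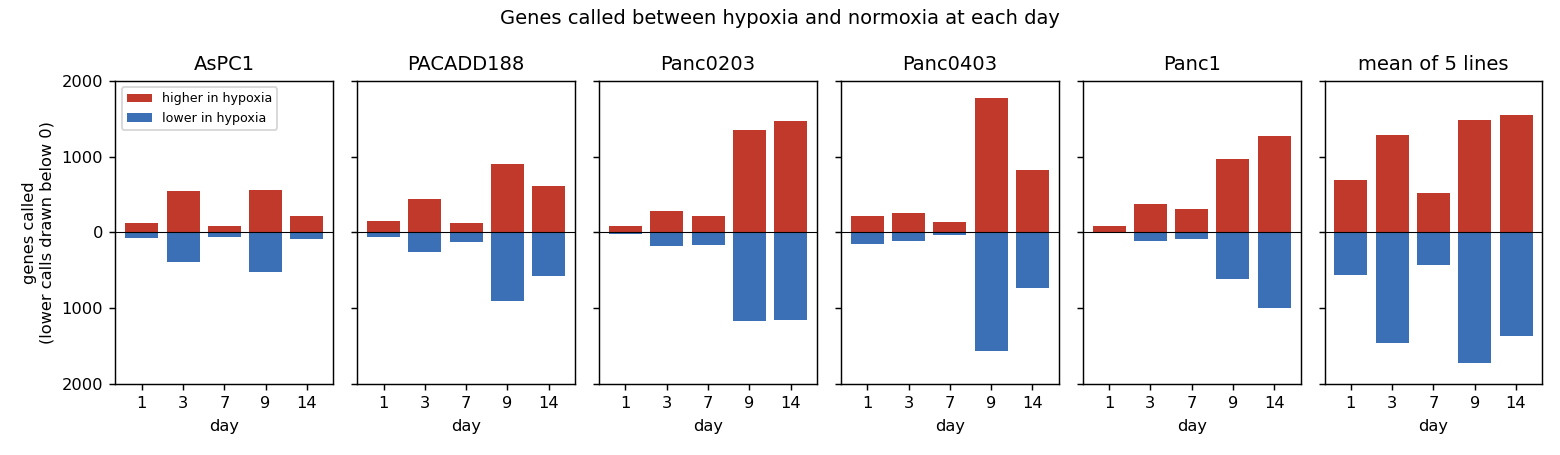
Number of genes called on each day, by cell line and for the mean of 5 lines, with genes higher in hypoxia drawn above 0 and lower ones below. Calls peaked on day 9 or day 14 in each line, at 3340 on day 9 in Panc0403, but with DESeq2 AsPC1 had 545 on day 3 and 543 on day 9.

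Seen day by day in the mean of lines, the HIF targets were up from day 1 on (log2 fold change ± SE). CA9 stood at 4.18 ± 0.53, 4.97 ± 0.44, 3.48 ± 0.38, 4.42 ± 0.56 and 3.88 ± 0.36, NDRG1 at 2.65 ± 0.11, 3.24 ± 0.12, 3.28 ± 0.12, 3.23 ± 0.099 and 4.02 ± 0.11 and SLC2A1 at 1.09 ± 0.047, 1.30 ± 0.049, 1.17 ± 0.05, 1.63 ± 0.047 and 1.68 ± 0.051 on days 1, 3, 7, 9 and 14. VEGFA was at 0.89 ± 0.094, 1.20 ± 0.09, 1.04 ± 0.09, -0.061 ± 0.079 and 0.79 ± 0.089, and its day 9 value, lowered by Panc0403, was not called (adjusted p = 0.691, edgeR). HIF1A was at -0.37 ± 0.071, -0.48 ± 0.073, -0.62 ± 0.072, -0.54 ± 0.071 and -0.71 ± 0.08, and EPAS1 at -0.097 ± 0.074, -0.10 ± 0.073, -0.63 ± 0.072, -0.36 ± 0.068 and -0.35 ± 0.077, not called on days 1 and 3 (adjusted p = 0.515 and 0.38, edgeR). Of the other values EPAS1 on day 14 had the highest adjusted p, 0.000361 (edgeR). Calls numbered 1263, 2746, 964, 3208 and 2921 of 14312 on days 1, 3, 7, 9 and 14.

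The hypoxia effect differed between lines for 4155 of 14312 genes (edgeR F test over the 5 line effects, adjusted p below 0.05). TFF3 rose in AsPC1 alone among the 3 lines where it was tested (3.02 ± 0.074, from 23.0 ± 6.68 to 193 ± 101 CPM, F test q = 4.66e-18). APOL1 rose by 2.85 ± 0.12 there and by 2.06 in Panc0403 and 0.75 in Panc1 (5.38e-27). The metallothioneins MT1G and MT1X fell in AsPC1 (-2.37 ± 0.14 and -1.39 ± 0.096; 9.89e-13 and 3.58e-46), whereas MT1X rose in the 4 other lines, by up to 2.48 in Panc0203. In PACADD188 the gap junction gene GJB2 (2.18 ± 0.077, 6.91e-20, also 0.61 in AsPC1 and 0.39 in Panc0403) and CD274, which encodes the checkpoint ligand PD-L1, rose (1.87 ± 0.14, 9.7e-09, also 0.83 in Panc0203), the latter from 8.99 ± 7.04 to 27.1 ± 10.0 CPM. AKR1C2 fell there (-3.05 ± 0.076, 5.13e-08, also -1.07 in AsPC1, -1.25 in Panc0403 and, with the library carrying PACADD188 transcripts, -2.23 in Panc0203, adjusted p = 0.0537), as did TFF1 (-2.17 ± 0.54, 4.65e-07), which rose by 1.23 in AsPC1 and 1.25 in Panc0403. Panc0203 stood out with ACKR3 (5.36 ± 0.77, 2.24e-08, also 3.40 in Panc0403), the mitophagy gene BNIP3 (2.53 ± 0.098, 0.000842, also 2.10 in Panc1), PTGES (-1.74 ± 0.068, 1.1e-24, also -0.58 in Panc0403) and DIO2 (-3.19 ± 0.98, 0.034, also -0.24 in PACADD188). DIO2 includes the library carrying PACADD188 transcripts, and its F test lost the call under 7 of 19 alternatives. The F test of BNIP3 was not called without PACADD188 replicate 2 nor without replicate 2.

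Panc0403 stood out with CA9 (6.23 ± 0.20, F test q = 3.15e-17, also 2.46 to 4.52 in the 3 other lines tested), the amino acid transporter SLC6A14 (1.53 ± 0.18, 8.75e-08, against -0.98 in PACADD188) and the peptide hormone ADM2 (-2.12 ± 0.36, 0.000283). GAS6-DT was also selected by the F test (0.0319), but its own change there was -0.17 ± 0.20 (adjusted p = 0.587). In Panc1 the mTOR inhibitor DEPTOR (2.45 ± 0.13, 6.1e-15) and the G protein subunit GNG4 (2.88 ± 0.22, 2.16e-10, also 0.24 in AsPC1) rose, while GJB2 fell (-1.14 ± 0.15, from 19.8 ± 11.9 to 7.92 ± 3.07 CPM). MAP7D2 (6.98e-05) did not change in Panc1 itself (-0.27 ± 0.17, adjusted p = 0.273) and rose by 2.52 in Panc0203, edgeR, a call lost without replicate 2. Thinning and leaving out replicate 2 each ended the F test calls of ADM2 and MAP7D2, and thinning that of ADM2 in Panc0403. Of the 9777 genes tested in all 5 lines, 130 were up and 33 down in all 5, where lists drawn independently would share 0.1606 and 0.1055. Another 606 genes were called up in 1 line and down in another, out of 5615 called in any. Without Panc1 replicate 2 the F test called 3457 genes.

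**Figure D3:**
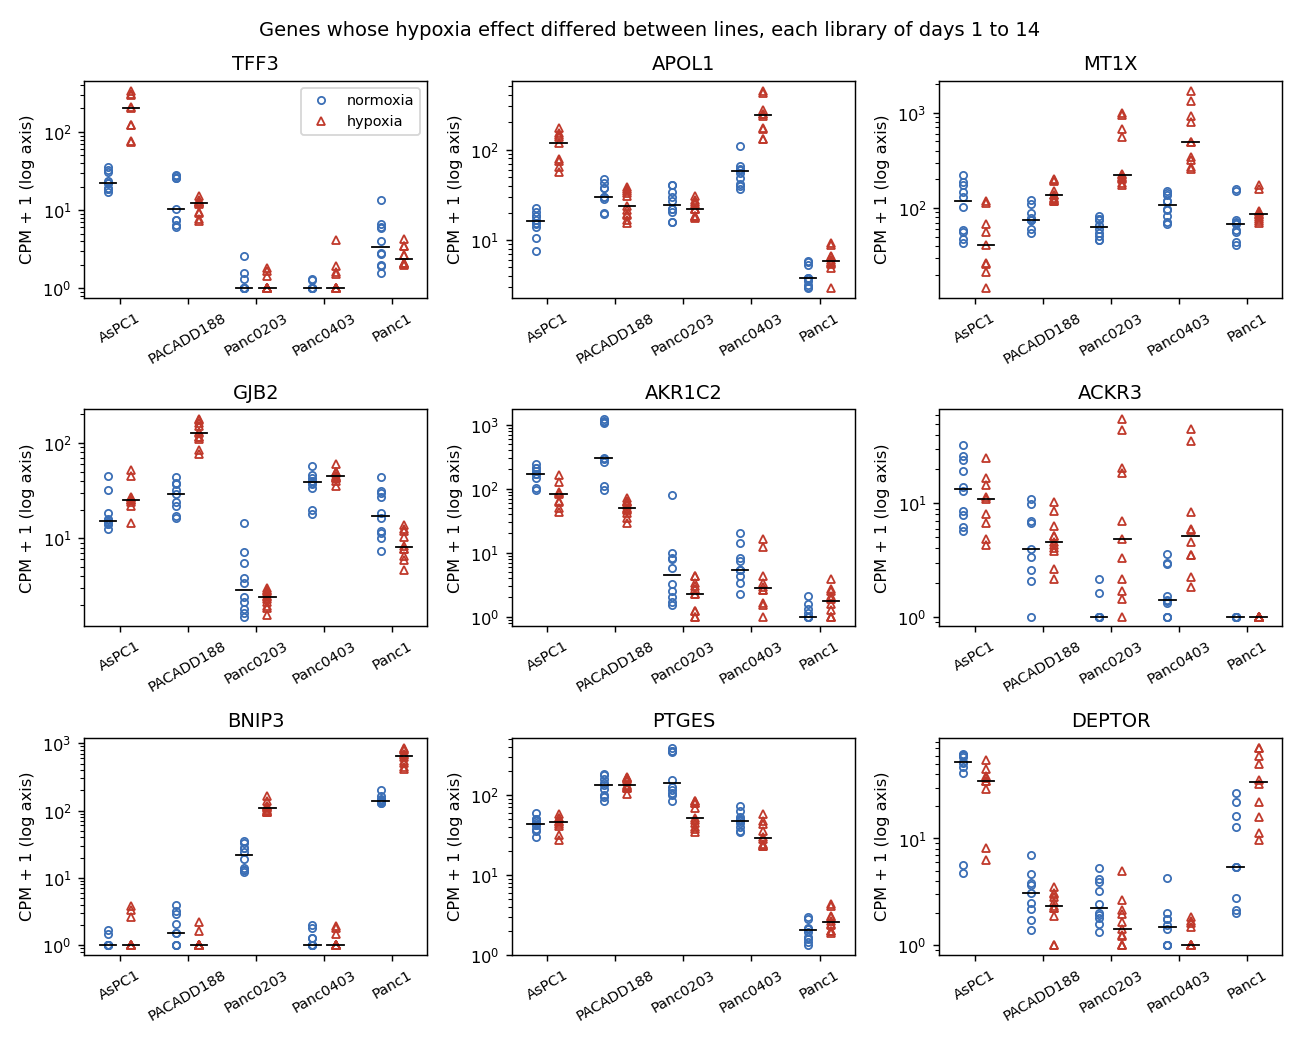
CPM + 1 (log axis) of 9 genes selected by the F test, with a point for each hypoxic and normoxic library of days 1 to 14 by cell line and a bar at the median. MT1X lay lower in hypoxia in AsPC1 and higher in the 4 other lines, and GJB2 was higher in hypoxia in PACADD188 and lower in Panc1.

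The hypoxia effect on day 14 differed from that on day 1 for 1658 of 14312 genes in the mean of lines, 932 higher and 726 lower. The ubiquitin ligase MARCHF4 went from 0.08 ± 0.15 on day 1 to 3.59 ± 0.33 on day 14, STC1 from 1.17 ± 0.35 to 4.38 ± 0.23 and ANGPTL4 from 2.10 ± 0.17 to 4.37 ± 0.27. TNFAIP3, an inhibitor of NF-kB, went from -0.21 ± 0.12 to 1.64 ± 0.19, TMEM158 from 0.58 ± 0.088 to 2.38 ± 0.12 and PAG1 from 1.12 ± 0.19 to 2.80 ± 0.19. The laminin chain LAMC2 moved from -0.15 ± 0.12 to 1.47 ± 0.20, and the centromere chaperone HJURP from -0.0021 ± 0.072 to 1.42 ± 0.083. In the other direction LXN went from 0.71 ± 0.12 to -1.59 ± 0.091, GDF15 from 0.30 ± 0.27 to -1.72 ± 0.17, S100P from 0.049 ± 0.16 to -1.83 ± 0.12 and AGR2 from 0.32 ± 0.082 to -1.54 ± 0.076. THSD7A fell from 0.47 ± 0.28 to -1.34 ± 0.30, KLHL24 from 0.69 ± 0.20 to -1.09 ± 0.14, the retinal reductase DHRS3 from 0.40 ± 0.13 to -1.22 ± 0.11 and the epithelial factor ELF3 from 0.68 ± 0.24 to -0.83 ± 0.17. STC1 had the highest adjusted p of these genes, 0.00283, in edgeR, and STC1 was not called without Panc0403 replicate 3. Each difference between days combines the hypoxic and the normoxic cultures of both days.

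NDRG1 and SLC2A1 grew with time (1.37 ± 0.17 and 0.58 ± 0.07, day 14 minus day 1, adjusted p = 1.75e-09 and 8.57e-10, edgeR). SLC2A1 lost its call without replicate 2. HIF1A fell further (-0.34 ± 0.11, adjusted p = 0.0267, not called without replicate 1 at 0.0556). CA9 (-0.30 ± 0.38), VEGFA (-0.097 ± 0.13) and EPAS1 (-0.25 ± 0.11) were not called (0.799, 0.823 and 0.136). Among groups, G2/M rose (40 of 40 up, 40 list-adjusted, q = 2.11e-54), the marker MKI67 by 1.30 ± 0.15 and CDC20 by 1.20 ± 0.14, while the normoxic list mean of Panc0203 dropped to 5.15 and 4.94 on day 14 from 7.07 and 6.94 on day 1. DNA replication rose with it (29 of 40 up, 32 list-adjusted, q = 1.75e-25), RRM2 by 1.08 ± 0.17, and DNA repair (13 of 20 up, 13 list-adjusted, q = 8.91e-10), FANCI by 1.03 ± 0.12. Ribosome biogenesis rose (12 of 27 up, 18 list-adjusted, q = 1.69e-09), as did glycolysis (11 of 21 up, 14 list-adjusted, q = 5.76e-11), HK2 by 0.84 ± 0.19. Other HIF targets (10 up and 2 down of 38, 13 and 2 list-adjusted, q = 0.00109) and matrix genes rose as well (7 of 30 up, 7 list-adjusted, q = 0.00166). Mitochondrially encoded genes fell (9 of 11 down, 10 list-adjusted, q = 6.7e-16), MT-ND2 by -0.76 ± 0.12, and oxidative phosphorylation (20 of 63 down, 26 list-adjusted, q = 1.8e-10, adjusted p = 0.0615 with an estimated correlation). ATF4 targets fell (9 of 20 down, 13 list-adjusted, q = 2.31e-06), PSAT1 by -1.22 ± 0.14, and fatty acid synthesis (1 up and 4 down of 13, 1 and 5 list-adjusted, q = 0.00268), SCD by -1.25 ± 0.12, all by camera. The classical list was lower (1 of 22 down, 1 list-adjusted, q = 2.78e-06) and was not called with the plate as a block (0.258). The unfolded protein response was called only then (0.167 without it, 0.0333 with the plate as a block).

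By line, the day 14 minus day 1 difference was called for 31 genes in AsPC1, 571 in PACADD188, 1585 in Panc0203, 349 in Panc0403 and 892 in Panc1. Leaving out 1 library gave as few as 12 (AsPC1 hypoxia day 1 replicate 3), 316 (PACADD188 hypoxia day 14 replicate 2), 1062 (Panc0203 normoxia day 1 replicate 2), 174 (Panc0403 hypoxia day 1 replicate 3) and 540 (Panc1 normoxia day 14 replicate 2). With the plate as a block AsPC1 had 66. AsPC1 has 1 hypoxic library on day 14, which leaves its count the least supported of the 5.

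**Figure D4:**
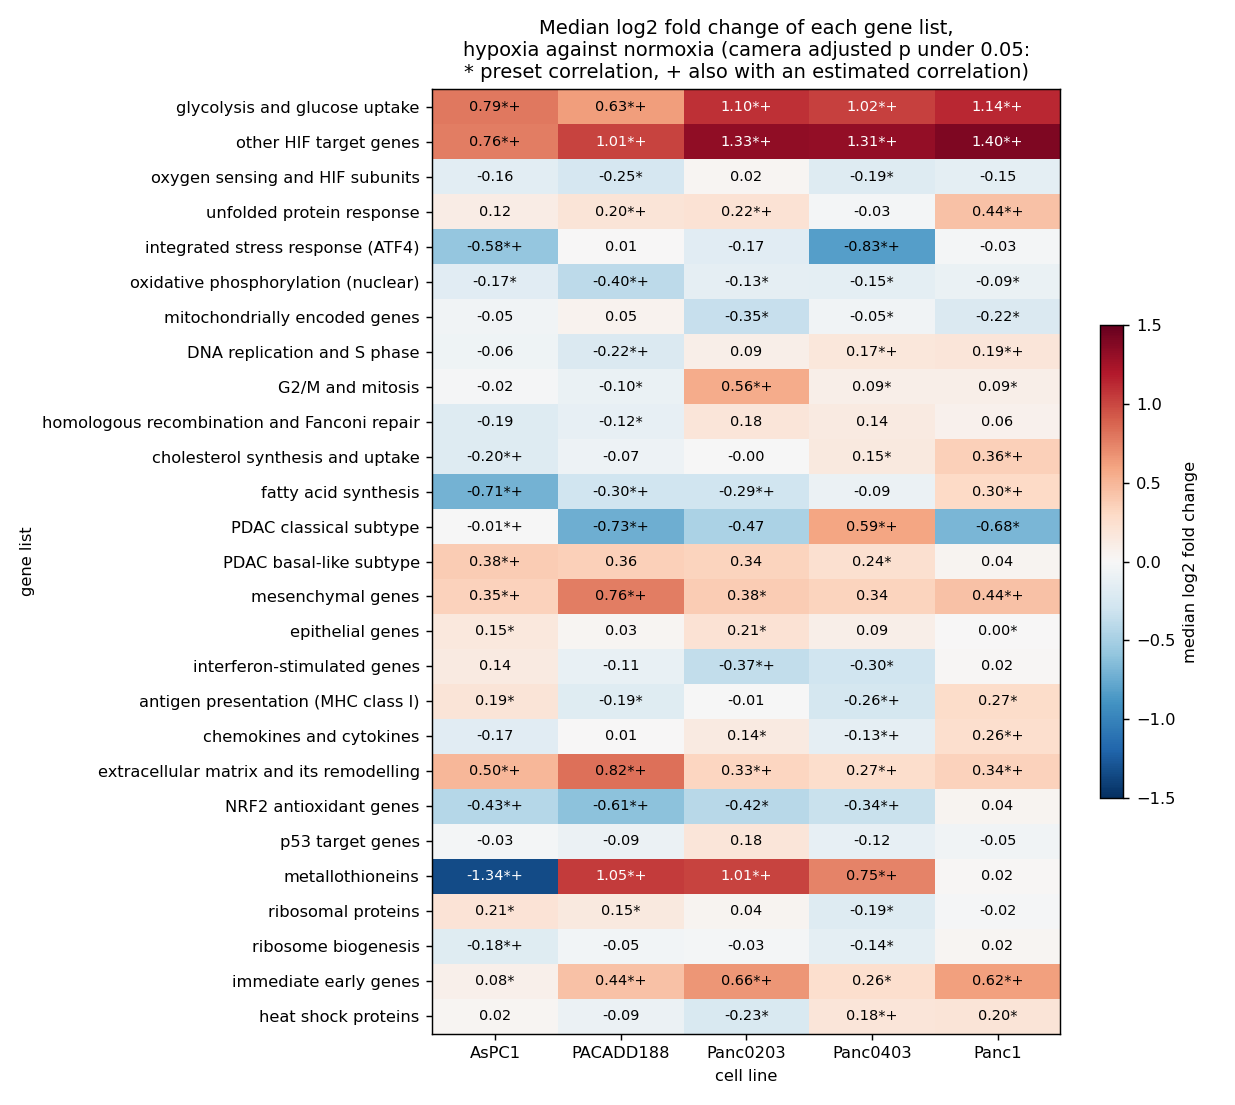
Median log2 fold change, hypoxia against normoxia, of the tested genes of each list in each cell line, where 1 asterisk marks camera calls with the preset correlation and a plus sign those that also held with an estimated one. Glycolysis and other HIF target lists were positive in every line, and the fatty acid and metallothionein lists changed sign between lines.

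At day 0 in normoxia each line was set against the mean of the other 4, with 2 libraries of AsPC1, Panc0403 and Panc1 and 3 of PACADD188 and Panc0203. Lines differ here together with their growth media. AsPC1 (7167 of 14312 genes called) carried the intestinal cadherin CDH17 at 674 ± 12.7 against 0.201 to 1.37 CPM in the other lines (SD, range of line means), the proteoglycan VCAN at 1205 ± 118 against 0.112 to 11.3 and LINC02864 at 56.3 ± 1.65 against 0. It lacked PHGDH, the first serine synthesis enzyme (0 against 31.0 to 81.2), the glutamine synthetase GLUL (0 against 16.2 to 76.2) and PGAP4 (0 against 17.2 to 74.3). Classical genes were higher (17 of 22 up, 17 list-adjusted, q = 4.11e-15), the lectin LGALS4 at 305 ± 50.1 against 0.184 to 1.57 CPM, and mucins with them (5 up and 1 down of 7, 5 and 1 list-adjusted, q = 0.000624). ATF4 targets were lower (19 of 20 down, 19 list-adjusted, q = 4.95e-11), and so were MHC class I genes (10 of 13 down, 10 list-adjusted, q = 4.68e-08), HLA-B at 7.74 ± 0.456 against 119 to 526 CPM, all by camera. The ATF4 list mean of Panc0203, Panc0403 and Panc1 was 6.12 to 6.78 on day 0. On normoxic day 1 it was 4.41 to 5.05, and 4.94 and 5.09 in AsPC1. The other HIF target list was lower (6 up and 14 down of 38, 6 and 14 list-adjusted, q = 0.0425, adjusted p = 0.241 with an estimated correlation) and was not with the plate as a block (q = 0.0606).

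PACADD188 (7532 called) carried DIO2 at 526 ± 18.6 against 0.112 to 1.76 CPM in the other lines, the proteoglycan decorin (DCN) at 140.1 ± 4.84 against 0 to 0.444 and SIRLNT at 48.7 ± 5.62 against 0. It had little of the epithelial splicing factor ESRP1 (0 against 4 to 220.0), the lactate dehydrogenase LDHB (0 against 0.504 to 942) or COL18A1 (0 against 3.5 to 242). Epithelial genes were lower (16 of 20 down, 16 list-adjusted, q = 1.71e-16), EPCAM at 3.86 ± 2.35 against 41.7 to 978 CPM. Mesenchymal genes were higher (16 of 20 up, 16 list-adjusted, q = 2.31e-09), the fibrillin FBN1 at 85.8 ± 7.96 against 0 to 1.07. So were NRF2 genes (18 up and 1 down of 22, 18 and 1 list-adjusted, q = 3.98e-09), AKR1C2 at 257 ± 17.0 against 0 to 73.9 CPM, all by camera.

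Panc0203 (7932 called) carried the microRNA host transcript MIR205HG at 488 ± 42.4 against 0 to 1.12 CPM in the other lines, the protease inhibitor TIMP3 at 231 ± 26.2 against 0 to 0.463 and the oxidase NOX5 at 129 ± 5.25 against 0 to 0.301. It lacked DLC1 (0 against 6.94 to 176), PCDH7 (0.246 ± 0.426 against 44.0 to 158) and IRF7 (0 against 6.32 to 36.0). Basal-like genes were higher by camera (16 of 20 up, 16 list-adjusted, q = 6.44e-12), UCA1 at 251 ± 52.8 against 0 to 104 CPM. Epithelial (15 of 20 up, 15 list-adjusted, q = 1.25e-10) and cytokine genes were higher too (18 up and 2 down of 27, 19 and 2 list-adjusted, q = 6e-07), CSF2 at 69.0 ± 6.68 against 0 to 7.91 CPM. With the plate as a block, oxidative phosphorylation lost its call (q = 0.0347 without, 0.0847 with the plate as a block), and G2/M (0.0566 and 0.0461) and ribosomal proteins (0.447 and 0.0168) gained one.

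Panc0403 (7565 called) carried the keratins KRT81 and KRT6B at 6927 ± 454 against 0.915 to 6.67 and 68.9 ± 0.292 against 0 to 0.419 CPM in the other lines and the pseudogene CLEC4OP at 52.0 ± 0.0699 against 0 to 0.0984. It lacked the fatty acid elongase ELOVL5 (0 against 48.7 to 238), CD109 (0 against 31.6 to 124) and COL6A1 (0 against 10.7 to 111). DNA replication genes were lower (40 of 40 down, 40 list-adjusted, q = 3.72e-26), TYMS at 5.92 ± 3.65 against 156 to 324 CPM, and G2/M genes (40 of 40 down, 40 list-adjusted, q = 5.8e-25), the mitotic cyclin CCNB1 at 45.1 ± 4.37 against 172 to 298. Basal-like (18 up and 2 down of 20, 18 and 2 list-adjusted, q = 2.02e-16) and epithelial genes were higher (19 of 20 up, 19 list-adjusted, q = 8.4e-18). ATF4 targets were higher (18 of 20 up, 18 list-adjusted, q = 7.37e-10), TRIB3 at 319 ± 2.64 against 16.4 to 204 CPM, all by camera.

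Panc1 (8312 called) carried the mitochondrial protein EFHD1 at 80.3 ± 4.78 against 0 CPM in the other lines, the helicase DDX43 at 73.6 ± 1.96 against 0 and the chemokine CCL2 at 155 ± 6.98 against 0 to 0.283. It lacked the epithelial genes SERPINB5 (0 against 33.4 to 262), CEACAM6 (0 against 7.18 to 1639) and SLPI (0 against 47.0 to 139). Basal-like genes were lower by camera (2 up and 12 down of 20, 2 and 13 list-adjusted, q = 9.74e-06), FAM83A at 0.229 ± 0.00711 against 13.4 to 471 CPM. Interferon genes were lower too (7 up and 24 down of 36, 7 and 24 list-adjusted, q = 0.00131), IFI27 at 0.341 ± 0.151 against 1.12 to 415 CPM. The classical list was lower (2 up and 9 down of 22, 2 and 9 list-adjusted, q = 0.0135, adjusted p = 0.0591 with an estimated correlation) and was not with the plate as a block (q = 0.055). Of the day 0 genes named for the 5 lines LDHB in PACADD188 had the highest adjusted p, 6.34e-07 (edgeR).

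Normoxic culture alone moved many genes between day 0 and day 14. In AsPC1 (2877 of 11634 called) the gluconeogenic enzyme PCK1 rose by 7.18 ± 0.91, the ketone synthesis enzyme HMGCS2 by 6.30 ± 0.34 and ARHGEF38 by 5.18 ± 0.88 (log2 fold change ± SE, 2 libraries on each day). CRISPLD2, the stress kinase SGK1 and MARCHF4 changed by -4.10 ± 0.44, -3.40 ± 0.61 and -3.15 ± 0.49. Cholesterol synthesis rose (21 of 24 up, 22 list-adjusted, q = 1.71e-26), INSIG1 by 2.33 ± 0.17, and fatty acid synthesis (8 of 12 up, 8 list-adjusted, q = 5.29e-11). Metallothioneins (7 of 7 down, 7 list-adjusted, q = 7.21e-18) and immediate early genes fell (1 up and 8 down of 15, 1 and 8 list-adjusted, q = 1.09e-08), all by camera. SGK1 had the highest adjusted p of these genes, 0.00037 (edgeR). Without normoxia day 0 replicate 2 the count was 1750.

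PACADD188 (1959 of 11815 called) raised the fatty acid carrier FABP4 by 2.82 ± 0.12, the phosphatase inhibitor PPP1R1B by 2.70 ± 0.44 and the pseudogene RPL26P19 by 2.73 ± 0.78. The last was not called without 1 library (0.47). The immediate early genes FOSB, FOS and EGR1 changed by -6.00 ± 0.50, -4.54 ± 0.27 and -3.50 ± 0.17, the group with them (12 of 15 down, 14 list-adjusted, q = 9.36e-36). NRF2 genes (11 up and 1 down of 21, 13 and 1 list-adjusted, q = 3.72e-14), AKR1C2 by 2.17 ± 0.13, rose by camera. RPL26P19 had the highest adjusted p of these genes, 0.0184 (edgeR, 3 libraries on day 0 and 2 on day 14). Without normoxia day 14 replicate 3 the count was 758.

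Panc0203 (3018 of 12420 called) raised the stress factor NUPR1 by 3.41 ± 0.41, the cell death gene BMF by 3.18 ± 0.47 and the surface antigen PSCA by 3.17 ± 0.17. SYT14, MARCHF4 and the long noncoding RNA MANCR changed by -4.60 ± 0.86, -4.09 ± 0.48 and -6.84 ± 1.67. G2/M genes fell (40 of 40 down, 40 list-adjusted, q = 9.37e-70), BUB1 by -2.41 ± 0.20, and DNA replication (32 of 40 down, 35 list-adjusted, q = 5.23e-20). Immediate early genes fell (14 of 15 down, 14 list-adjusted, q = 3.19e-19), and interferon genes rose (17 up and 1 down of 35, 17 and 1 list-adjusted, q = 2.4e-08), MX1 by 1.65 ± 0.21, all by camera. The plate as a block took the call from oxidative phosphorylation (q = 0.039 without, 0.117 with) and gave one to mesenchymal genes (0.0971 and 0.0483). MANCR had the highest adjusted p of these genes, 0.00425 (edgeR, 3 libraries on day 0 and 2 on day 14). Without normoxia day 14 replicate 3 the count was 1581.

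In Panc0403 (2973 of 11841 called) G2/M genes rose from a low day 0 level (40 of 40 up, 40 list-adjusted, q = 7.65e-78), CCNA2 by 2.88 ± 0.16. DNA replication genes rose with them (38 of 40 up, 39 list-adjusted, q = 3.33e-41), TYMS by 3.61 ± 0.25. The MYC antagonist MXD3 rose by 5.27 ± 0.84, the histone gene H1-3 by 4.65 ± 0.44 and PCSK9, which degrades the LDL receptor, by 4.59 ± 0.54. LINC01564, EGR1 and ADGRF4 changed by -5.30 ± 0.83, -4.64 ± 0.22 and -4.21 ± 0.78. Cholesterol synthesis rose (18 of 24 up, 20 list-adjusted, q = 4.39e-16), and immediate early genes fell (12 of 15 down, 14 list-adjusted, q = 7.17e-24), all by camera. ADGRF4 had the highest adjusted p of these genes, 0.000291 (edgeR, 2 libraries on each day).

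Panc1 (1415 of 11668 called) raised the catenin ARVCF by 2.81 ± 0.47, FOXD3-AS1 by 2.69 ± 0.53 and the histone gene H1-2 by 2.22 ± 0.48. The dynein regulator DRC3, FOS and SBNO1-AS1 changed by -8.09 ± 1.20, -4.39 ± 0.25 and -3.58 ± 0.93. G2/M genes fell (38 of 40 down, 40 list-adjusted, q = 4.56e-49), KIF20A by -1.74 ± 0.23, and DNA replication (26 of 40 down, 34 list-adjusted, q = 2.25e-26), MCM2 by -1.66 ± 0.24. Immediate early genes, a handling marker, fell (2 up and 5 down of 16, 4 and 7 list-adjusted, q = 5.44e-05). ATF4 targets rose (7 of 20 up, 8 list-adjusted, q = 4.82e-05), DDIT3 by 1.23 ± 0.19, all by camera. SBNO1-AS1 had the highest adjusted p of these genes, 0.0152 (edgeR, 2 libraries on each day). Without normoxia day 14 replicate 2 the count was 585, and ARVCF, FOXD3-AS1, H1-2 and SBNO1-AS1 were not called.

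**Figure D5:**
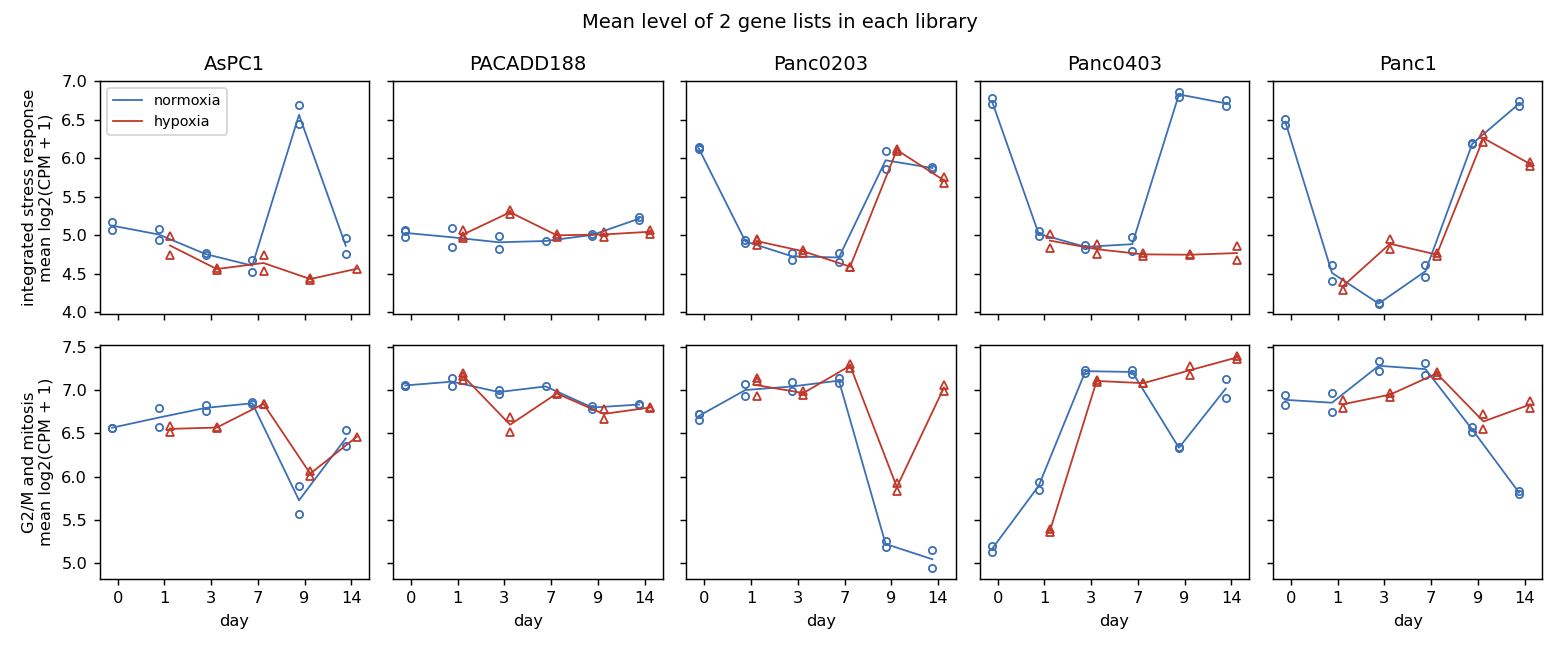
Mean log2(CPM + 1) of the ATF4 and the G2/M gene lists against day in each cell line, with a point for each normoxic and hypoxic library and lines through the group means. ATF4 targets were higher on day 9 than on day 7 in 4 lines in normoxia and in Panc0203 and Panc1 in hypoxia, and G2/M genes fell to day 14 in normoxic Panc0203 and Panc1.

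The share of counts in mitochondrially encoded genes was lower in hypoxic than in normoxic AsPC1, 6.27 ± 0.293% against 6.73 ± 0.316% (SD, n = 9 and 10, adjusted p = 0.0161, permutation test, 2-sided). It was 4.04 ± 0.981% against 4.46 ± 1.18% in PACADD188, 3.68 ± 0.764% against 4.70 ± 1.13% in Panc0203, 4.13 ± 0.738% against 4.50 ± 1.03% in Panc0403 and 3.05 ± 0.92% against 3.50 ± 1.05% in Panc1, with adjusted p from 0.061 to 0.481. Ribosomal protein genes took a larger share in hypoxic AsPC1 (9.99 ± 0.89% against 8.87 ± 0.557%) and a smaller one in hypoxic Panc0403 (8.02 ± 0.692% against 9.10 ± 0.756%, adjusted p = 0.0161 for both, permutation test). They did not differ in PACADD188 (11.7 ± 1.28% against 11.1 ± 1.26%), Panc0203 (10.8 ± 0.901% against 10.8 ± 0.772%) or Panc1 (8.37 ± 0.647% against 8.58 ± 0.935%), with adjusted p from 0.481 to 0.981. The share tests treat libraries of different days as replicates and were adjusted over 10 tests. Fold changes averaged over days correlated between lines, across genes, at Pearson r from 0.303 to 0.468 (median 0.44, 10 pairs of lines). Between days within a line the median r was 0.29 in AsPC1, 0.32 in PACADD188, 0.118 in Panc0203, 0.169 in Panc0403 and 0.334 in Panc1 (10 pairs each). Genes are not independent replicates, so no p-value is given.

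Some of the genes named share sequence with relatives, so their counts may be mixed: AKR1C1 with AKR1C2, SLC2A3 with SLC2A14, the MT1 genes with each other, KRT6B and KRT81 with other keratins, and H1-2 with H1-3. Of 136 genes named by rule, 5 overlap an exon of another counted gene on the same strand and 21 on the opposite strand. Bulk RNA of a culture gives transcript levels, not protein or HIF activity, and does not separate cell states within a line.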

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

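The 2 tests of PACADD188 transcripts in a Panc0203 library were chosen only after the result was seen. The groups hold 1 to 3 libraries, so none was tested for an outlying library.

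An effect that differed between lines or days by its own test is listed here. Between lines 4155 genes differed in the F test. Between day 14 and day 1 the hypoxia effect differed for 31 genes in AsPC1, 571 in PACADD188, 1585 in Panc0203, 349 in Panc0403, 892 in Panc1 and 1658 in the mean of lines. The line effects (log2 fold change) were 3.02 for TFF3, 2.85 for APOL1, -2.37 for MT1G and -1.39 for MT1X in AsPC1. In PACADD188 they were 2.18 for GJB2, 1.87 for CD274, -3.05 for AKR1C2 and -2.17 for TFF1. In Panc0203 they were 5.36 for ACKR3, 2.53 for BNIP3, -3.19 for DIO2 (with the library carrying PACADD188 transcripts) and -1.74 for PTGES. In Panc0403 they were 6.23 for CA9, 1.53 for SLC6A14, -2.12 for ADM2 and -0.17 for GAS6-DT, and in Panc1 2.45 for DEPTOR, 2.88 for GNG4, -1.14 for GJB2 and -0.27 for MAP7D2. From day 1 to day 14 the effect moved by 3.51 for MARCHF4, 3.21 for STC1, 2.28 for ANGPTL4, 1.85 for TNFAIP3, 1.80 for TMEM158, 1.68 for PAG1, 1.62 for LAMC2 and 1.42 for HJURP. It moved by -2.30 for LXN, -2.02 for GDF15, -1.88 for S100P, -1.86 for AGR2, -1.81 for THSD7A, -1.78 for KLHL24, -1.63 for DHRS3 and -1.50 for ELF3. Outside the comparisons, the control of plate 3 held 146 counts and the library left out for its depth 17173 counts.

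Regrouping tested whether chance grouped the libraries, with oxygen labels exchanged within a day (60 splits per line, the real one included). In AsPC1, PACADD188, Panc0203, Panc0403 and Panc1 only 1 of 60 splits, the real one, gave as many calls: 2306 against at most 619, 2821 against 721, 2787 against 1577, 2444 against 1900 and 2392 against 160 in the others. In the fit of all libraries 1 of 24 splits, the real one, reached the mean of lines (4524 against 304) and days 1, 3, 7, 9 and 14 (1263, 2746, 964, 3208 and 2921 against 1, 108, 37, 411 and 1149). With lines exchanged at day 0 it was 1 of 24 for PACADD188 (7532 against 6415) and Panc0203 (7932 against 6648). Chance is argued against by line, but 24 splits are too few to tell. Those at day 0 still set lines apart. For the F test (4155 against 336) and day 14 minus day 1 (1658 against 518), exchanging oxygen removes the effect itself, so these splits do not test whether it differed between lines or days.

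The Panc0203 library of normoxia day 7 replicate 2 held the 9 genes that mark PACADD188 at a median of 34.4% of their PACADD188 level. PACADD188 RNA there would raise all of them, and they stood at 22.4 to 68.8%. Reads of all lines spreading between wells are argued against, as markers of the 3 other lines stood at most at 0.491%. Over 28 day 7 genes of Panc0203 nearly absent from PACADD188, this library kept a median of 68.7% of their level. Whether cells, RNA or cDNA were mixed stays open, and no biological explanation was tested.

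Hypoxic libraries were shallower in each line. After thinning to equal totals 54.8 to 79.7% of the 2-fold calls and 48.9 to 78.3% of all calls were kept. Among all calls 1 gene, in Panc1, turned its sign. Thinning also costs power, so a part of the calls that came from depth cannot be told apart, and no biological explanation was tested. Exchanged oxygen labels among kept libraries are argued against, since 0 of 100 pairs of a hypoxic and a normoxic library of the same line and day had a lower glycolysis mean in hypoxia.

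ATF4 targets stood higher in normoxia on day 9 than on day 7, and in Panc0203 and Panc1 in hypoxia too. The normoxic rise was on both plates in 4 of 5 lines, which argues against a single plate. Immediate early genes moved by a median of 1.239 in AsPC1, 0.3454 in Panc0403, 0.1415 in Panc0203 and -0.0191 in Panc1, so handling before lysis cannot be told apart from a change in the cultures. Feeding and density are not recorded, and no biological explanation was tested.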

How the results depend on the processing

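Chosen only after the counts had been seen were the tests with all libraries as labelled, with the shallow library kept, without the Panc0203 library carrying PACADD188 transcripts, without single libraries and without 1 line on 1 plate. Most groups held 2 libraries, and a lone library is assumed to vary like the other groups. Of 53 counts of called genes none moved over 1.5 times with RLE scaling or the stricter filter. None of 21 did with the shallow library kept, and none of 5 when a line was read from the fit of all libraries. DESeq2 moved 11, no filter 11, thinning 35, the compared libraries alone 9 of 25 and the labels as deposited 53. Leaving out replicate 1 moved 2, replicate 2 moved 26 of 29 and replicate 3 moved 19 of 22. Only 4 replicate 1 libraries were kept, all of PACADD188 or Panc0203. Leaving out replicate 1 therefore could not move the counts or named values from fits of AsPC1, Panc0403 or Panc1 alone. Without replicate 2 or 3 no fit of AsPC1, Panc0403 or Panc1 alone could be made, and without replicate 3 the mean of lines lacked groups. Of 376 values of named genes 364 were called, and 175 of these kept call and sign under every alternative. Over 8220 alternatives 278 calls were lost, 2 were gained and 2 called values turned. Of the 12 not called, 5 changed sign under some alternative. With all libraries as labelled, PSAT1 stood at 0.010 (day 14 minus day 1) and MANCR at 0.42 (Panc0203, normoxic time). Calls also ended without 1 library for DIO2 in Panc0203 and VEGFA in Panc0403 (both above) and EPAS1 in Panc1 (hypoxia day 14 replicate 3). For normoxic time they ended without day 14 replicate 2 for MANCR in Panc0203 and ARVCF, FOXD3-AS1, H1-2 and SBNO1-AS1 in Panc1. In the F test DIO2 was not called without Panc1 replicate 2 nor GAS6-DT without PACADD188 replicate 2. HIF1A for day 14 minus day 1 was not called in 6 of 9 fits without 1 line on 1 plate, and in AsPC1 it gained a call without normoxia day 9 replicate 3. Thinning ended 25 calls, beside those above LAMB3 and VHL (mean of lines), EPAS1 (day 9, Panc0203, Panc1), GDF15 (day 14 minus day 1), SLC6A14 in PACADD188, ACKR3 in Panc0203, VEGFA (Panc0403 days 1 and 3), NDRG1 (Panc1 day 1), DIO2 (F test), LDHB (day 0), RPL26P19 and FOXD3-AS1. Leaving out replicate 2 ended 24, among them HK2 and PAG1 (day 14 minus day 1), and EPAS1 and OAS2 in Panc0203, which also lost theirs without replicate 3.

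Counts follow in the order mean of days, days 1, 3, 7, 9 and 14, day 14 minus day 1, normoxic day 14 against day 0, and day 0 against the other lines. For the mean of lines the last 2 are replaced by the difference between lines. In AsPC1 the counts were 2306, 198, 932, 145, 1082, 309, 31, 2877 and 7167. As labelled AsPC1 gave 231, 0, 0, 0, 10, 0, 0, 6 and 2948. Thinned, AsPC1 gave 1926, 163, 807, 99, 836, 263, 25, 2200 and 4448. Leaving libraries out gave 1986 to 2310, 49 to 227, 323 to 932, 50 to 145, 503 to 1082, 155 to 309, 12 to 31, 1750 to 2877 and 4218 to 7174. In PACADD188 the counts were 2821, 206, 695, 253, 1815, 1195, 571, 1959 and 7532. As labelled PACADD188 gave 1486, 24, 5, 0, 164, 63, 0, 0 and 3869. Thinned, PACADD188 gave 1986, 115, 391, 126, 1173, 963, 368, 1166 and 4704. Leaving libraries out gave 1127 to 2897, 66 to 164, 64 to 805, 55 to 300, 218 to 1952, 226 to 1259, 28 to 539, 220 to 1777 and 5337 to 7459. In Panc0203 the counts were 2787, 109, 466, 387, 2520, 2633, 1585, 3018 and 7932. As labelled Panc0203 gave 912, 0, 0, 0, 99, 240, 0, 1 and 3492. Thinned, Panc0203 gave 2061, 73, 250, 213, 1933, 2227, 1236, 2389 and 4705. Leaving libraries out gave 728 to 2796, 23 to 167, 30 to 553, 41 to 620, 373 to 2650, 804 to 2781, 247 to 1513, 952 to 2788 and 5544 to 7846. In Panc0403 the counts were 2444, 361, 380, 181, 3340, 1569, 349, 2973 and 7565. As labelled Panc0403 gave 304, 5, 0, 0, 5, 45, 0, 2 and 1662. Thinned, Panc0403 gave 1308, 270, 133, 66, 1666, 818, 1.7e+02 (rounded), 1718 and 5040. Leaving libraries out gave 2128 to 2541, 176 to 361, 103 to 380, 39 to 181, 2114 to 3340, 865 to 1569, 174 to 376, 1998 to 2973 and 4950 to 7612. In Panc1 the counts were 2392, 95, 490, 390, 1587, 2273, 892, 1415 and 8312. As labelled Panc1 gave 436, 0, 0, 7, 17, 32, 0, 1 and 3587. Thinned, Panc1 gave 1438, 55, 279, 193, 863, 1623, 487, 772 and 5140. Leaving libraries out gave 2023 to 2392, 55 to 95, 176 to 490, 216 to 390, 878 to 1587, 1185 to 2273, 540 to 892, 585 to 1415 and 5673 to 8311. In the mean of lines the counts were 4524, 1263, 2746, 964, 3208, 2921, 1658 and 4155. As labelled the mean of lines gave 2609, 248, 730, 96, 552, 577, 0 and 413. Thinned, the mean of lines gave 2635, 560, 1272, 337, 1482, 1724, 871 and 2034. Leaving libraries out gave 1967 to 4547, 107 to 1213, 332 to 2823, 141 to 1022, 708 to 3247, 1010 to 2993, 220 to 1631 and 686 to 4298. In the 19 results where all libraries as labelled called 0 genes in edgeR, 173 to 1659 genes had an unadjusted p below 0.05.

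At least 2-fold were 206, 306, 305, 208 and 243 genes in the 5 lines and 88 in the mean of lines. DESeq2 gave AsPC1 1387 (mean of days), 129 (day 1), 545 (day 3), 92 (day 7), 543 (day 9), 180 (day 14), 1556 (normoxic time) and PACADD188 447 (day 3), 1158 (day 9), 369 (day 14 minus day 1), 1222 (normoxic time). Its share of rising genes was 76.7 against 65.2% in AsPC1 on day 1, 44 against 68.9% in Panc0403 on day 3 and 56.5 against 46.2% in the mean of lines on day 9. No filter gave AsPC1 533 (day 1), 274 (day 7), 543 (day 14), 174 (day 14 minus day 1), PACADD188 387 (day 1), Panc0203 300 (day 1), 713 (day 3), 745 (day 7), Panc0403 693 (day 3), 415 (day 7) and Panc1 197 (day 1). The compared libraries alone gave AsPC1 55 (day 7), PACADD188 77 (day 1), Panc0203 879 (day 3), 118 (day 7), Panc0403 70 (day 1), 253 (day 3) and Panc1 61 (day 1), 255 (day 3), 150 (day 7). The Panc0203 library carrying PACADD188 transcripts left out gave Panc0203 190 (day 7).

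The plate as a block gave AsPC1 347 (day 1), 66 (day 14 minus day 1), Panc0203 1041 (day 3), 619 (day 7) and Panc0403 567 (day 1), 642 (day 3), 345 (day 7). The other counts moved by less than 1.5 times, and no named gene gained or lost a call.

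Gene lists called moved in 6 of 17 contrasts with an estimated correlation: for day 0 Panc0203 8 against 14, Panc1 4 against 14, and for hypoxia Panc0203 9 against 16, Panc0403 11 against 21, Panc1 10 against 17, and for normoxic time Panc1 5 against 9. With fry, which tests each list by itself, they moved in 7 of 17: for day 0 AsPC1 25 against 15, PACADD188 25 against 13, Panc0203 24 against 14, Panc0403 25 against 16, Panc1 24 against 14, and for normoxic time PACADD188 19 against 12, Panc0403 24 against 14. The block moved none. With all libraries as labelled the mitochondrial share changed by -0.320 points in AsPC1 (adjusted p = 0.529) and -0.936 in Panc0203 (0.049), and the ribosomal protein share by 0.856 in AsPC1 (0.061, permutation tests). Leaving out single libraries moved the mitochondrial share of Panc0203 between -1.22 and -0.793 points, called in 4 cases (adjusted p from 0.0155 to 0.121, permutation test). No median correlation of fold changes moved by more than the spread of its pairs.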

Other observations

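The tests of normoxic day 9 against day 7 were chosen only after the stress genes had been seen to differ. BNIP3 was nearly silent in 3 of the 5 lines. It averaged 112 CPM in hypoxic and 20.9 CPM in normoxic Panc0203 and 639 and 147 CPM in Panc1, while AsPC1, PACADD188 and Panc0403 stood at 0.116 to 1.01 CPM. All 7 metallothioneins tested differed between lines, and the line medians (log2 fold change) ran from -1.34 in AsPC1 to 1.05 in PACADD188.

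Between normoxic days 7 and 9, ATF4 targets rose in AsPC1 (15 of 16 called up, median 1.64), Panc0203 (15 up and 1 down of 20, 1.35), Panc0403 (19 of 20 up, 1.94) and Panc1 (18 of 20 up, 1.68, edgeR). In PACADD188, with 1 library on day 7, 1 of 18 was called (0.12). Over all genes the 2 days differed for 2864, 3713, 4299, 1505 and, in PACADD188, 547 genes. The list mean (log2 CPM + 1) rose in hypoxia too in Panc0203 (4.59 and 4.60 to 6.13 and 6.09) and Panc1 (4.77 and 4.73 to 6.21 and 6.31).

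The PACADD188 library left out for its depth held 8 counts on 7 of 9 PACADD188 markers and 31 counts on 4 of 5 Panc0403 markers.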
